A study of Mus musculus with 2 samples.

How the data were processed

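DNase-seq of whole ovary was analysed for 2 libraries of aged female B6CASTF1/J mice, which form a single group in the labels. Per the file headers and the text files deposited with the samples, each library came with 2 lists of narrow peaks, a list of footprints and a list of bases with a false discovery rate of the cut rate, all on mouse build mm10 and derived from that library's own alignments without pooling. The aligner, the peak caller, the footprint caller and their versions are not given in the sources used here. The reads are from a hybrid of C57BL/6 and CAST, and how CAST alleles were mapped to the reference is not given in the sources used here.

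The strength column of the deposited peak lists is a signal that the authors scaled for depth. All values (100%, within 0.05 of a step) were whole multiples of 1 step per library, 0.0108 in replicate 1 and 0.00782 in replicate 2, which fits counts divided by a factor of the library; the target depth is not stated. Each peak's signal is thus the authors' own value, and it was used to describe and rank peaks, and to compare replicates at shared regions. The p-value and q-value columns of the deposited peak lists hold no values. The deposited false discovery rates are listed only below 0.05. They were used to find how the peak lists differ: every peak of the longer lists contains a base below 0.05, and every peak of the shorter lists a base below 0.001, which 66.2% and 63.0% of the longer lists' peaks contain. Deposited footprints carry the constant p-value label 0.01, whose kind is not stated.

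The longer list was the main list, with 95898 and 83982 peaks, and the shorter list, with 60823 and 50503, was an alternative. Chromosome lengths of the files fit assembly GRCm38.p6, and genes came from GENCODE M21. Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, Matplotlib 3.10.9 and BLAST 2.17.0. Peaks overlapped if they shared at least 1 bp. Promoters were the 500 bp either side of any annotated transcription start of a protein-coding gene, and a gene's promoter signal was that of its strongest such peak. Peaks not at promoters were assigned to exons, introns or intergenic sequence in that order. Chromosome Y was left out of all tests because the animals were female, and its peaks are described with the results that deserve a closer look.

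Overlap and genomic classes were tested against 1000 random rotations along each chromosome. Gene lists were tested with Fisher's exact test on the share of genes with a promoter peak in both replicates, and against 10000 random lists matched in 10 bins of the CpG ratio at the annotated 5′ end of the gene. Sites in the gene body and 10 kb either side were compared with 10000 random lists matched in 20 bins of length. Footprint overlap was tested by 1000 rotations within shared regions. Peaks with at least 1 footprint were searched for 34 consensus sequences on both strands without mismatch. The density of match centres in footprints was divided by that in the rest of the peak, with a pseudocount of 0.5 and 1000 rotations of the matches within the peak. Adjusted p-values are Benjamini-Hochberg values over all lists or all sequences, with a threshold of 0.05.

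The lists, the sequences, the tests and most alternatives were fixed before the data were examined. Genes named in the text are 32 fixed genes, the 2 members of each list with the strongest promoter peak by mean rank over both replicates, and the 5 strongest shared regions more than 2 kb from a protein-coding start; sequences named are the 5 highest and 3 lowest past the threshold in both replicates. Genes or sequences outside this rule, such as Gja1, Kitl, Npm2, Ooep, NR5A, GATA and TEAD, were chosen after their values were seen. Members with near-identical copies (Hsd3b1, Hsd3b6, Hba-a1, Hbb-bt, Serpina1a and Dppa5a) are uncertain, since reads can map to several copies. Some genes and a sequence that this rule takes in are not reported here.

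Alternatives were the shorter lists, equal numbers of peaks, the strongest 20000 peaks, a reciprocal overlap of 50%, wider promoters and flanks, other backgrounds for lists and sequences, and each replicate left out. The tests on peaks, lists, footprints and sequences were tested on simulated data. With 30% of 83934 peaks planted, the overlap test returned 31.1%, and 0 of 20 independent lists were called. The promoter test over 21728 genes recovered 50 of 50 lists planted with 1 of 14 genes open and called 0 of 200 random lists. Lists matched on CpG ratio recovered 20 of 20 such planted lists and called 0 of 60 random lists and 0 of 60 lists of genes with a low CpG ratio. The test of signal ratios between replicates, over 13527 genes, recovered 19 of 20 lists of 17 genes shifted by 0.5 log2 units and called 0 of 60 random lists. The class test made 4 calls in 20 rotated peak lists of 4 classes each, at an unadjusted threshold of 0.05, and recovered 20 of 20 lists with 10% of peaks moved to promoters. The footprint test found 54.8% overlap where 50% had been planted among 2000 regions. A sequence planted in footprints of 2000 simulated peaks was recovered, with 0 of 3 others called. Region signals were returned exactly in 1000 of 1000 simulated regions.

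With 2 libraries, SDs rest on 2 values, and no test across animals was made. Comparing young with aged ovaries or cell types with one another is not analysed here.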

Results

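Accessible chromatin was measured in the whole ovary of aged female mice by DNase-seq, in which DNase I cuts open DNA and the cut ends are sequenced. The animals were B6CASTF1/J, first-generation hybrids of C57BL/6 and CAST mice, and were 18 to 20 months old. There was 1 group with 2 libraries, which the labels call biological replicates 1 and 2. They carry separate biosample entries under the same donor entry. Whether they came from the same animal or from different animals is not given in the sources used here, so their spread is not shown to be a spread between animals. The p-values and intervals given here measure only these 2 libraries. No younger or other tissue was part of the series, so the data answer which sites were open in this tissue and how well the replicates matched, and no change with age was tested. Peak signal was deposited in steps of 0.0108 in replicate 1 and 0.00782 in replicate 2. The step of replicate 1 was 1.38 times as large, so replicate 2 was the deeper library if both were scaled to the same depth. The absolute depth is unknown.

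The longer peak list of each library held 95898 peaks in replicate 1 and 83982 in replicate 2, a mean of 89940 ± 8426 (SD, n = 2). These peaks covered 18.2 and 16.0 Mb of the mouse genome (build GRCm38), or 0.667% and 0.587% of it. Promoters, taken as 500 bp either side of a protein-coding transcription start, held 25.7% ± 1.63 of the peaks (SD, n = 2), against 2.48% for the same peaks rotated along their chromosomes. Exons held 5.44% ± 0.144 against 4.14% rotated. Introns held 31.4% ± 0.977 against 34.2%, and intergenic sequence held 37.5% ± 0.795 against 59.2%. Each of the 4 classes differed from its rotated share with a two-sided permutation p of 0.0020, the smallest that the 1000 rotations can give. The promoter share depended on which peaks were counted, and among the strongest 20000 peaks of each replicate it was 57.4%.

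**Figure D1:**
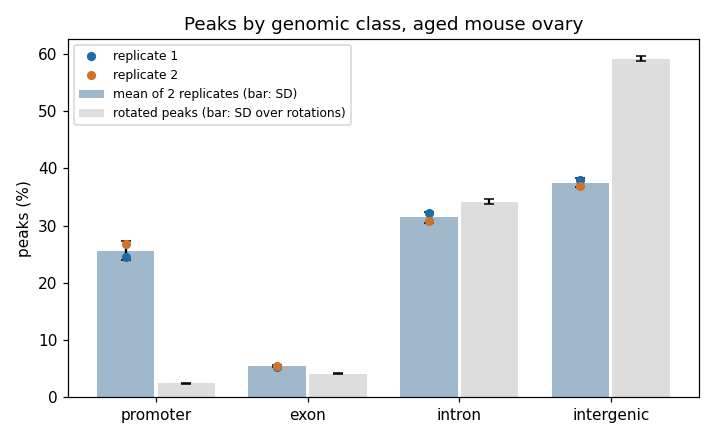
Share of peaks (%, vertical axis) in 4 genomic classes, for each replicate (points), their mean with SD (blue bars) and peaks rotated along the chromosomes with the SD over rotations (grey bars). Promoters held 25.7% of the peaks against 2.48% after rotation, and intergenic sequence 37.5% against 59.2%.

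Both libraries shared most of their sites. Of the replicate 1 peaks 68.9% overlapped a replicate 2 peak by at least 1 bp, and of the replicate 2 peaks 78.5% overlapped a replicate 1 peak. After rotation the latter share was 1.42% on average and at most 1.60% (one-sided permutation p = 0.000999, the smallest possible with 1000 rotations). The 112418 regions of the combined lists comprised 64875 shared regions, 29642 of replicate 1 only and 17901 of replicate 2 only. Shared regions had a median signal of 1.12 in replicate 1 and 0.977 in replicate 2. Regions of replicate 1 only had a median of 0.484, and those of replicate 2 only 0.469. Promoters made up 29.9% of the shared regions, 12.3% of those of replicate 1 only and 15.2% of those of replicate 2 only. Across shared regions, which are not independent replicates, the authors' signal correlated between the libraries with a Spearman coefficient of 0.859 and a Pearson coefficient of 0.904 on log2 values. The log2 ratio of replicate 2 to replicate 1 had a median of -0.03 and an SD of 0.56, and 91.4% of the shared regions lay within 2-fold of that median.

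Of 21728 protein-coding genes on the autosomes and the X chromosome, 13527 (62.3%) had a promoter peak in both replicates. Another 892 had a promoter peak in 1 replicate only. A peak counted at any annotated start, and at some genes the strongest lay inside the gene, more than 500 bp from its annotated 5′ end. Among these were Nr5a2, Gata4, Cyp11a1, Cyp19a1, Esr1, Pdgfra, Lhx9, Cdkn1a, Ptch1, Por, Vwf, Lck, Pax5 and Plin1. Actb, Dazl, Epor, Krt10 and Krt1 were others. Transcription factors of the ovarian somatic lineage were among the open genes. Foxl2, a granulosa cell factor that maintains ovarian identity (chromosome 9, 98955288 to 98958543), had a promoter signal of 4.05 ± 0.334 (SD, n = 2). Nr5a1, which encodes the steroidogenic factor SF-1 (chromosome 2, 38692656 to 38714542), had 3.91 ± 0.365. Gata4 had 7.41 ± 1.37, Gata6 3.35 ± 0.900, Nr5a2 2.87 ± 0.644 and Wt1 4.02 ± 1.22. Inha, the inhibin alpha subunit, had 5.02 ± 1.18, and Amh, which encodes anti-Müllerian hormone, had 1.49 ± 0.537.

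Several genes of steroid synthesis had promoter peaks, but the theca and steroidogenic list did not pass, with 9 of 12 genes open against 62.2% of other genes (exact test, adjusted p = 0.746). Star, which moves cholesterol into mitochondria, had a promoter signal of 5.83 ± 1.88 (SD, n = 2), and Scarb1, the receptor for high-density lipoprotein, had 3.51 ± 0.717. Cyp11a1 had 2.42 ± 0.252, Cyp17a1 1.95 ± 0.472, Lhcgr 1.49 ± 0.0874 and Cyp19a1, the aromatase gene, 0.883 ± 0.198. No promoter peak was listed for Hsd3b1 in either replicate; it has near-identical family members, and reads that map to several of them could be lost. Of the estrogen receptors, Esr2 had 1.42 ± 0.266, and Esr1 had 1.41 in replicate 1 and 1.56 in replicate 2. Pgr had 0.592 in replicate 1 and 1.02 in replicate 2. The strongest Esr1 promoter peak lay at different annotated starts in replicates 1 and 2. Fshr, the receptor for follicle-stimulating hormone, had a promoter peak of 0.430 in replicate 2 and none in replicate 1.

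Stromal genes Pdgfra and Tcf21 had promoter signals of 3.10 ± 0.811 and 1.03 ± 0.192 (SD, n = 2). The Pdgfra peak lay at an internal annotated start and held a CTCF match. Of the surface epithelium genes, Lhx9 had 0.837 ± 0.111, and Bnc1 had 0.527 in replicate 1 with no peak in replicate 2. The oocyte genes Zp3 and Nobox had no promoter peak in either replicate. Gdf9, an oocyte growth factor, had 13.5 ± 4.71, but its start lies 192 bp from that of Uqcrq, a gene of the respiratory chain, and both share the peak. Sox9, a Sertoli cell factor of the testis, had 3.26 ± 0.0785, whereas Dmrt1 had no promoter peak. The cell cycle inhibitors Cdkn1a and Cdkn2a had 3.90 ± 0.292 and 0.729 ± 0.202. Xist, the RNA gene of X inactivation, had 1.09 ± 0.310.

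**Figure D2:**
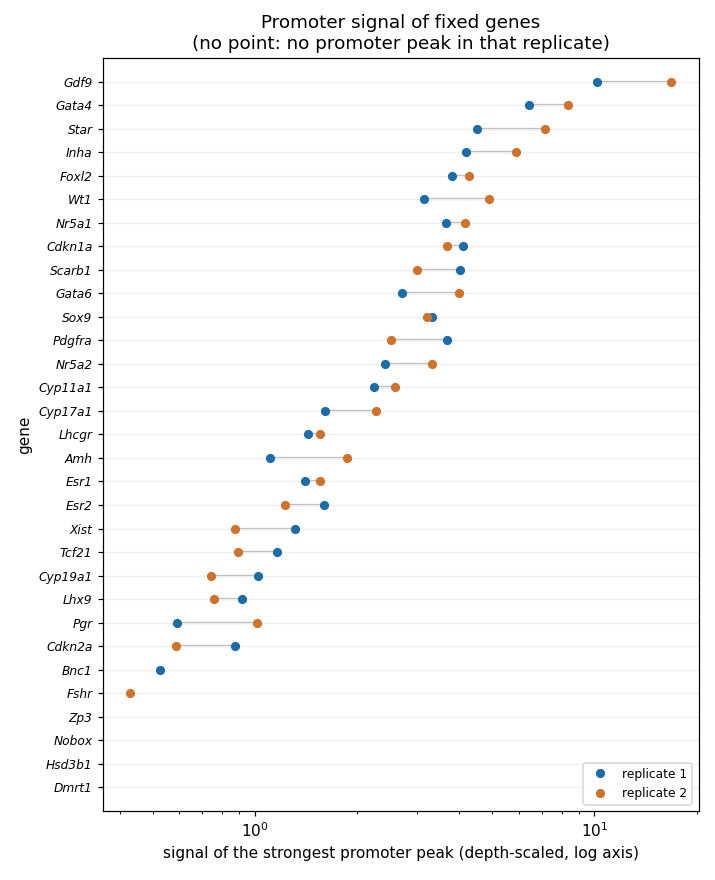
Signal of the strongest promoter peak (horizontal log axis, depth-scaled signal as the authors give it) of genes fixed before the data were examined, with 1 point per replicate. Gdf9, whose peak also covers the start of Uqcrq, is highest at 10.2 and 16.9, and Zp3, Nobox, Hsd3b1 and Dmrt1 have no point.

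Granulosa cell genes were open more often than other genes. Promoter peaks in both replicates were found at 17 of 18 granulosa genes (94.4%, against 62.2% of other genes), with Fshr as the exception. With the shorter peak lists the granulosa share was 77.8%, and its adjusted p in the exact test was 0.198. Besides Inha, Foxl2 and Amh, the open members included Gja1 (3.42 in replicate 1 and 4.70 in replicate 2) and Kitl (2.65 and 3.79). All 14 housekeeping genes and all 12 genes of cholesterol synthesis were open. Hmgcs1, an early enzyme of that pathway, had a promoter signal of 15.3 ± 5.55 (SD, n = 2), and Dhcr7, whose peak also lies near the start of Nadsyn1, had 14.2 ± 2.93. Rpl13a had 10.2 in replicate 1 and 15.8 in replicate 2, and Actb had 12.1 ± 2.84. In Fisher's exact test, two-sided with Benjamini-Hochberg adjustment over 26 lists, the adjusted p was 0.0129 for granulosa, 0.00869 for housekeeping and 0.0188 for cholesterol synthesis genes.

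Genes of oocytes, macrophages, T cells and liver were open less often than other genes. Of these calls, only that of the oocyte list stayed with lists matched on CpG ratio, as given below. Only 4 of 17 oocyte genes had a promoter peak in both replicates (23.5%, adjusted p = 0.00869 in the same exact test), and these were Gdf9, Dazl, Npm2 and Ooep. Of 13 macrophage genes 1 did, and the exact test gave an adjusted p of 0.000916; in replicate 1 alone the share was 23.1% and in replicate 2 alone 15.4%, with adjusted p of 0.0223 and 0.00594 in the exact test. Of 12 T cell genes 2 did, Lck (4.07 ± 0.490, SD, n = 2) and Tcf7 (2.07 ± 0.00243), with an adjusted p of 0.00869 in the exact test. None of 12 hepatocyte genes did (exact test, adjusted p = 0.000216). In replicate 1 alone 6 of the 17 oocyte genes were open, and that list's adjusted p was then 0.0558 in the exact test. With promoters of 2000 bp either side of a start, the T cell share was 33.3%, and its adjusted p in the exact test was 0.0978.

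Promoter peaks also depended on the CpG content of the promoter. Each list was thus set against 10000 random lists with similar observed-to-expected CpG ratios at the annotated 5′ end. A gene counted as open at any start, so CpG content at internal starts and the number of starts were not matched. Among granulosa genes, the strongest peaks of Nr5a2 and Cyp19a1 lay at internal starts. The granulosa list stayed higher (94.4% against 60.9%, permutation adjusted p = 0.0026) and the oocyte list lower (23.5% against 53.4%, permutation adjusted p = 0.0364). The housekeeping, cholesterol synthesis, macrophage, T cell and hepatocyte lists were no longer past the threshold, with permutation adjusted p of 0.117, 0.124, 0.229, 0.452 and 0.108. Hox genes were open less often than their matched lists. Of 16 Hox genes of paralog groups 9 to 13, which pattern the posterior body, 5 were open (31.2% against 88.3%, permutation adjusted p = 0.0026), among them Hoxd10 (3.16 ± 0.675, SD, n = 2) and Hoxc10 (2.95 ± 0.272). Of 23 Hox genes of groups 1 to 8, 12 were open (52.2% against 79.2%, permutation adjusted p = 0.0156), among them Hoxd8 (2.23 ± 0.0444) and Hoxa7 (2.10 ± 0.395). Stromal genes were open at 11 of 13 promoters (84.6% against 49.4%, permutation adjusted p = 0.0499), including Ptch1 (3.72 ± 0.158). In the exact test these calls were not made, with adjusted p of 0.0560 for Hox groups 9 to 13, 0.563 for groups 1 to 8 and 0.279 for stromal genes. Hox genes lie in clusters of close neighbours, such as Hoxd8 and Hoxd10 on chromosome 2. Both tests treated linked members as independent, and the random lists were drawn gene by gene. The p-values of the Hox lists may thus be too small.

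The other lists did not pass either test. Simulated lists were planted only as lower (1 of 14 open), so the power to call short lists as higher is unknown. Theca and steroidogenic genes were open at 9 of 12 promoters, led by Por (16.9 ± 5.69, SD, n = 2) and Fdxr (14.1 ± 2.61), 2 genes of electron transfer that are used in many tissues. Luteal genes were open at 6 of 8, led by Hsd17b7 (12.4 ± 3.34) and Cited4 (6.18 ± 0.215), and oviduct epithelium genes at 6 of 8, led by Foxj1 (6.10 ± 1.01) and Emx2 (3.98 ± 0.297). Smooth muscle and pericyte genes were open at 10 of 12, with Mylk at 4.95 ± 0.362 and Myh11 at 1.77 ± 0.219. Surface epithelium genes were open at 7 of 12, led by Aldh1a2, whose strongest promoter peak lay at different positions in the replicates, and Krt8. Endothelial genes were open at 7 of 13, with Vwf at 2.44 ± 1.26 and Sox18 at 1.87 ± 0.406. Genes of senescence and inflammation were open at 8 of 14, led by Il6 (5.67 ± 1.86) and Cdkn2b (5.12 ± 0.657). Extracellular matrix genes were open at 12 of 15, with Timp2 at 4.01 ± 0.0485 and Mmp14 at 2.98 ± 0.119.

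Lists of B cells (3 of 9, with Pax5 at 3.47 ± 0.214 and Ebf1 at 2.75 ± 0.215) and adipocytes (4 of 10, with Pnpla2 at 5.56 ± 0.200 and Plin1 at 1.24 ± 0.637) did not pass (SD, n = 2). Neither did erythroid cells (3 of 9, with Epor at 0.923 ± 0.0107) and Sertoli cells (6 of 9, with Sox8 at 2.68 ± 0.302), nor neurons (7 of 12, with Syp at 1.88 ± 0.294 and Tubb3 at 1.81 ± 0.164). Skeletal muscle genes were open at 4 of 12, with Actn3 at 1.29 ± 0.139 and Mylpf at 7.78 ± 4.23, whose peak also lies near the start of Tbc1d10b. Keratinocyte genes were open at 2 of 9, Krt10 (4.63 ± 0.504) and Krt1 (0.824 ± 0.0376), both at internal annotated starts. Pluripotency genes were open at 3 of 10, including Tdgf1 (1.49 ± 0.563) and Sox2 (0.699 ± 0.0928). With the shorter peak lists, the erythroid share was 11.1% and 1 of 10 pluripotency genes was open, and both lists then passed as lower, with adjusted p of 0.0167 and 0.00948 in the exact test. Hox groups 9 to 13 passed there too (exact test, adjusted p = 0.00347). In replicate 1 alone 2 lists not called in the main test passed, among them keratinocyte genes (exact test, adjusted p = 0.0389). With a background without olfactory receptor genes, 2 lists not called in the main test passed. Of the 26 lists, 10 had an unadjusted p under 0.05 in the exact test.

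**Figure D3:**
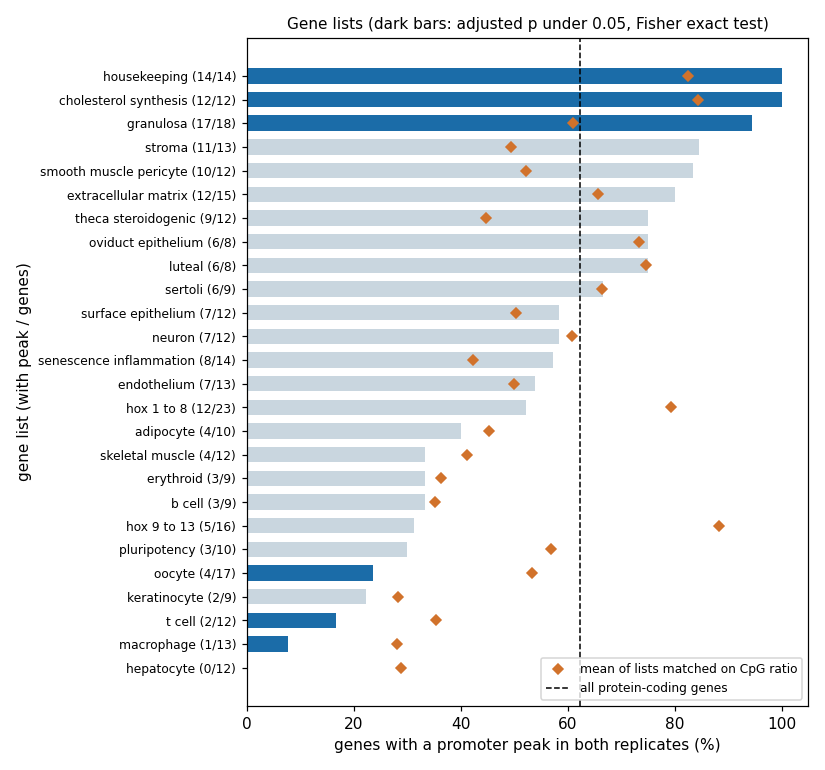
Share of genes with a promoter peak in both replicates (%, horizontal axis) for 26 gene lists, with the number of genes beside each name. Dark bars passed Fisher's exact test after adjustment (the hepatocyte list, at 0, passed too and shows no bar), diamonds give the mean of lists matched on CpG ratio, and the dashed line is the 62.3% of all genes.

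Sites around the genes were counted as well. Within the gene body and 10 kb either side, granulosa genes had a median of 4 shared regions, against 2.5 for random lists matched on length. Smooth muscle and pericyte genes had 4.5 against 3, Sertoli cell genes 4 against 2, macrophage genes 1 against 3 and oocyte genes 1 against 2. Scarb1 and Esr1 each had 17 shared regions in that window, Mylk 14 and Esr2 10. None of the 26 lists passed after adjustment (permutation test, two-sided), and 1, the housekeeping list, had an unadjusted p under 0.05, at 0.0230. On simulated data this test recovered 3 of 20 lists planted among 21728 genes from genes with at least 5 sites, so a count of 0 does not exclude differences of that size.

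Of the shared regions, 40065 (61.8%) lay more than 2 kb from any protein-coding transcription start. The strongest of these by mean rank was an intronic site of Mid1 on the X chromosome, 169997961 to 169998420, with a signal of 54.7 ± 13.4 (SD, n = 2). An exon of Cers5, a ceramide synthase gene, held the next one (chromosome 15, 99735641 to 99736060, 38.1 ± 5.95). A site inside an annotated ribosomal RNA gene (chromosome 17, 39846781 to 39846920) had 62.3 in replicate 1 and 27.9 in replicate 2. A pair of intergenic sites followed, on chromosome 13 (48546541 to 48546820, 19.4 ± 8.16) and on chromosome 5 (25529581 to 25529860, 18.1 ± 5.43), which lay 33.0 and 13.5 kb from the nearest protein-coding start. Near-identical copies were found for the Mid1 site on chromosome Y and for the ribosomal RNA site on the X or an autosome.

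Footprints, short stretches protected from cutting inside open sites, numbered 181762 in replicate 1 and 200993 in replicate 2. Their median width was 10 bp in both. Peaks contained 91.9% and 89.7% of them, and 71.5% of replicate 1 peaks and 81.6% of replicate 2 peaks held at least 1. Inside shared regions, 57.8% of replicate 1 footprints overlapped a footprint of replicate 2, and 51.0% of replicate 2 footprints overlapped a footprint of replicate 1. The mean of both directions was 54.4%, against 32.8% for footprints rotated within their regions. The highest of 1000 rotations gave 33.0% (one-sided permutation p = 0.000999, the smallest possible).

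Only peaks with at least 1 footprint were searched, 68020 in replicate 1 and 67922 in replicate 2. Over these peaks, the ratios of density in footprints were highest for sequences bound by NRF1, CTCF and cAMP-responsive factors. Shares of matches inside footprints leave out matches in peaks without a footprint. The NRF1 consensus GCGCATGCGC was 118 ± 17.2 times as dense in footprints as in the rest of the same peaks (SD, n = 2). Inside footprints lay 365 of its 384 matches in replicate 1 (95.1%) and 382 of 397 in replicate 2 (96.2%). Its ratio thus rests on few matches outside, and rotated matches gave 2.18 and 2.22. The CTCF consensus CCASYAGRKGGC, bound by an organiser of chromatin loops, reached 26.1 ± 4.96, with 84.0% and 81.1% of its matches inside. The cAMP response element had 17.1 ± 1.45, the consensus of the neuronal repressor REST 15.6 ± 6.54 and that of NFI 14.1 ± 3.38. Matches were few for REST (253 in replicate 1 and 145 in replicate 2) and NFI (108 and 100). DNase I cuts some sequences more readily than others, and no model of this preference was fitted, so each ratio holds protection and cutting preference together. Dividing by the ratio of the reversed sequence, which has the same bases in the opposite order, was the only allowance made for it. The order depended on the comparison: divided by the ratio of the reversed sequence, NRF1 had 49.3, slightly below CTCF, and REST had 2.83. In peaks more than 2 kb from a start, NRF1 had 42.9, REST 19.7, NFI 17.0 and the cAMP response element 8.77. The NR5A consensus YCAAGGYCA, recognised by the products of Nr5a1 and Nr5a2, had 3.17 ± 0.967, with 30.6% and 42.2% of matches inside footprints. Of 34 sequences, 16 were higher and 5 lower in footprints than after rotation in both replicates, with adjusted p of at most 0.0124 (permutation, two-sided, Benjamini-Hochberg). For those named as higher, the unadjusted permutation p was 0.0020 in each replicate, the smallest possible.

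Forkhead and POU sequences were among the least frequent in footprints. The forkhead consensus RTAAACA had a ratio of 0.313 ± 0.0212 (SD, n = 2) and the POU consensus ATGCAAAT 0.540 ± 0.0560. GATA and TEAD sequences were lower too, at 0.564 ± 0.0242 and 0.677 ± 0.0350. When each was divided by the ratio of its own reversed sequence, TEAD became higher (1.28, permutation adjusted p = 0.00893), and GATA and POU were no longer called in both replicates, while the forkhead sequence stayed lower but moved to 0.597 (permutation adjusted p = 0.00893).

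At promoters of the fixed genes, several matches lay in footprints of both replicates. The Amh promoter carried the NR5A sequence CCAAGGTCA on chromosome 10 at 80805148 to 80805156, with its centre at -91 bp from the start. Scarb1 carried TCAAGGCCA on chromosome 5 at 125326619 to 125326627, at -356 bp from an internal annotated start, and GCGTGGGCG, a sequence of the EGR and WT1 factors, at 125341143 to 125341151. Nr5a1 carried the E-box GTCACGTGG, bound by USF factors, on chromosome 2 at 38714584 to 38714592. Pdgfra carried the CTCF sequence CCACTAGAGGGC on chromosome 5 at 75156372 to 75156383, 479 bp downstream of an internal annotated start. This match lay in the peak that gave Pdgfra its promoter signal, 3.67 in replicate 1 and 2.52 in replicate 2. The SP and KLF sequence GGGGCGGGG lay in footprints at Gata4, Cdkn1a and Gdf9.

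**Figure D4:**
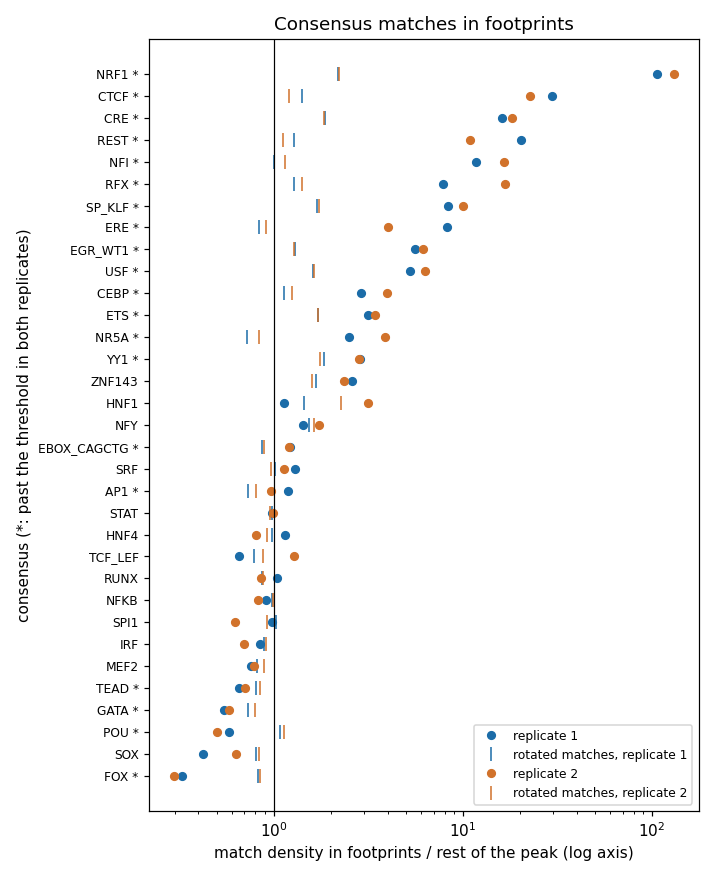
Density of consensus matches in footprints divided by that in the rest of the same peaks (horizontal log axis) for consensus sequences, with points for the replicates, ticks for the mean of rotated matches and a star for those past the threshold in both replicates. NRF1 lies at 118 and CTCF at 26.1 on average, while the forkhead sequence lies at 0.313.

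The X chromosome held fewer peaks for its length than any autosome. It had 14.2 ± 1.05 peaks per Mb (SD, n = 2), against 35.5 ± 3.35 over all autosomes, a ratio of 0.400 ± 0.00822. Protein-coding genes on the X were 0.656 times as dense as on autosomes. Autosomes ranged from 28.0 peaks per Mb on chromosome 3 to 52.8 on chromosome 11. No test was made, since chromosomes are not replicates.

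**Figure D5:**
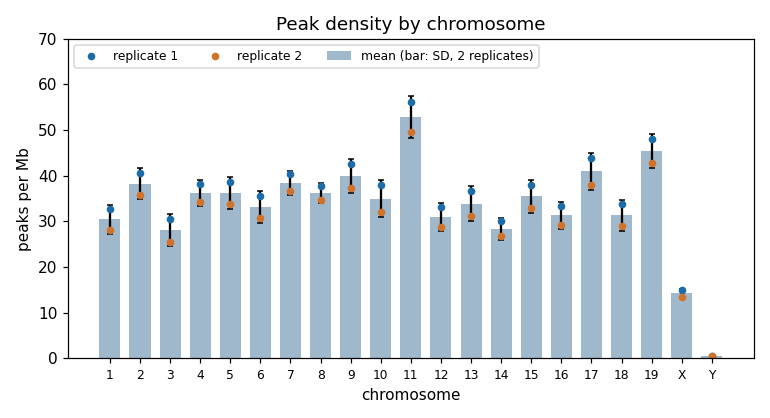
Peaks per Mb (vertical axis) for each chromosome, with bars for the mean, error bars for the SD and points for the 2 replicates. Chromosome 11 is highest at 52.8, the X chromosome stands at 14.2, and the Y chromosome at 0.469.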

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

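The NRF1 and REST tests, the split of chromosome Y at 90 Mb and the matching of promoter ratios on CpG content were chosen after the results they bear on had been seen, and the other tests before.

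Peaks were listed on chromosome Y although the tissue was female: 38 in replicate 1 and 48 in replicate 2, a signal outside the comparisons of the report. Of the 4 Y genes Ddx3y, Uty, Kdm5d and Eif2s3y, 0 had a promoter peak in either replicate, which argues against male tissue in the samples. Over both replicates 55.8% of the Y peaks had a near-identical copy on the X or an autosome (47.4% in replicate 1 and 62.5% in replicate 2, against 17.0% of 100 random Y windows), and since replicate 1 stayed under the 50% set beforehand, the source of the whole set could not be decided. Before 90 Mb 95.2% of 42 peaks had such a copy, and its reads may account for these, whereas beyond 90 Mb 18.2% of 44 did, which argues against copies in the assembly as the source of most of that block. Copies missing from the assembly stay open for it, and no biological explanation was tested.

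CTCF sites differed between the replicates, at 5.76% of all peaks in replicate 1 and 4.19% in replicate 2, and REST sites lay in 0.282% and 0.180% of them. Among the strongest 20000 peaks a CTCF match was 2.80 times as frequent in replicate 1 as in replicate 2, which argues against more and weaker peaks in replicate 1 as the source, and among the strongest 10000 distal peaks 2.65 times, which argues against a smaller distal share in replicate 2. REST matches had ratios of 2.45 and 2.77 in these sets, while NRF1 matches had 0.957 among the strongest 20000. Peaks with an NRF1 match were thus not fewer in replicate 2 (312 in replicate 1 and 326 in replicate 2). Among the strongest 10000 distal peaks only 26 of each replicate had an NRF1 match, so this test says little about distal sites. A weaker recovery of protected distal sites in replicate 2, with CTCF and REST among them, stays open. A different mix of cell types may contribute: 1 of 13 cell type lists passed, granulosa, whose promoters were higher in replicate 2 at 14 of 17 genes (median log2 ratio 0.46 against -0.01 for lists matched on signal, permutation adjusted p = 0.0026, and 0.0234 when matched on CpG ratio). Other lists were short in this test, down to 1 macrophage, 2 T cell and 3 B cell genes. Only lists of 17 genes were simulated, so shifts of those cell types are not excluded. That test concerns promoters and does not link the mix to CTCF sites, and differences in digestion or fragment size could not be tested and stay open, as does a biological difference between the samples.

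Some distal sites were very strong. None of the 5 strongest matched the mitochondrial genome (0 of 5), which argues against that source. A second copy in the assembly was found for 2 of the 5, against 0 of 100 random distal regions: that of the Mid1 site lies on chromosome Y, which a female genome lacks, and that of the ribosomal RNA site on the X or an autosome. Such copies may therefore raise only the ribosomal RNA site, while the Cers5 site and the intergenic sites on chromosomes 13 and 5 had none; 3 of 5 had been set as the number needed, and copies collapsed in the assembly were not tested, so the question stays open. No biological explanation was tested.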

How the results depend on the processing

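The background without olfactory receptor genes and the peaks without a CTCF match were chosen after seeing the data; the other alternatives were planned. Overlap of peaks, the promoter share and overlap of footprints kept their direction and stayed past the threshold in permutation tests under every alternative run, at 63.1% to 80.6%, 24.5% to 57.4% and 38.4% to 69.3%. With the shorter lists there were 55663 peaks on average, the Spearman coefficient was 0.865 and the X to autosome density ratio 0.381; the Pearson coefficient on log2 signal was 0.904. Between 5 and 9 gene lists passed for promoters, and none for nearby sites under any of 5 alternatives. With the shorter lists the granulosa list was no longer called (77.8%, adjusted p = 0.198, exact test). Matching on CpG ratio ended 5 of the 7 promoter calls and added 3. The number of consensus sequences past the threshold ranged from 19 to 24. Divided by the reversed sequence, the ratio changed side of the ratio of rotated matches for GATA (0.928), TEAD (1.28), SPI1 (5.97) and POU (1.36), and TEAD and SPI1 were then called as higher; the SP and KLF sequence equals its own reverse and has no such value. In peaks more than 2 kb from a start, YY1 changed side in the same sense (1.84) and was not called. Apart from these constructions, the cause was not tested. Leaving out replicate 1 or 2 gave 83982 to 95898 peaks, 181762 to 200993 footprints and an X to autosome ratio of 0.395 to 0.406; without replicate 2, the oocyte list was no longer called (adjusted p = 0.0558, exact test). Absolute depth is unknown, so how many weak sites were missed cannot be given.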

Other observations

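The values in this part were chosen after the data had been seen. Distal regions with a CTCF match were lower in replicate 2 at 96.7% of 2996 shared regions, with a median log2 ratio of replicate 2 to replicate 1 of -0.94. Regions with a REST match had a median of -0.98 over 91 regions. All 40065 distal shared regions had a median of -0.09, those with an NR5A match 0.13 and those with a GATA match 0.09. A CTCF match was present in 6.57% of the regions of replicate 1 only, 0.179% of those of replicate 2 only and 5.56% of the shared ones. The NR5A consensus was present in 4.31% of the regions of replicate 1 only, 5.91% of those of replicate 2 only and 8.01% of the shared ones. The ratios are between 2 libraries and carry no test.

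Distal sites lay in dense clusters at some genes. The strongest cluster by summed signal was at Mid1 on the X chromosome (169969821 to 169999520), with 19 shared sites. It includes the strong Mid1 site described above, which has a near-identical copy on chromosome Y. That site gave 45.2 of the summed 102.7 in replicate 1 and 64.2 of 121.0 in replicate 2. Firre, a noncoding RNA gene of the X chromosome, held the next one (50537224 to 50635520) with 31 sites and a summed signal of 98.9 in replicate 1 and 60.5 in replicate 2. Other clusters lay at Kdm6b on chromosome 11 (15 sites), Socs3 (12 sites) and Rara (11 sites), both on chromosome 11, and Malat1 on chromosome 19 (5 sites).

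Promoters with few CpG dinucleotides were open far less often, counted here only at the annotated 5′ end of each gene and not at its internal starts. Of 7896 genes with an observed-to-expected CpG ratio under 0.35 there, 748 (9.47%) had a peak in both replicates within 500 bp of that end, against 83.5% of 13832 other genes. By mean rank, the strongest of these 5′ ends without another protein-coding start nearby were those of Tef, a clock-controlled transcription factor, with a signal of 16.1 ± 5.61 (SD, n = 2), Gstm7 with 14.4 ± 4.58 and Tldc1 with 14.4 ± 0.571. Star was among them at 5.83 ± 1.88, as were Hsd3b7 at 5.64 ± 0.599 and Cish at 7.01 ± 0.0844. Of 1134 olfactory receptor genes 7 had a promoter peak in both replicates.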
